A study of Drosophila melanogaster with 4 samples.

How the data were processed

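Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of RNA polymerase II was carried out on CME-W1-Cl.8+ cells, a Drosophila melanogaster line known as Clone 8. Per the labels, the line is male and derives from the dorsal mesothoracic disc, the wing disc, of the third larval instar. Cells were fixed with formaldehyde and the chromatin was sheared by sonication, per the labels' protocols. The antibody was a mouse monoclonal against the heptad repeat YSPTSPS of the carboxy-terminal domain of the largest polymerase subunit. The series holds 4 samples, namely 2 ChIP replicates and 2 input DNA libraries. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures, so standard deviations may measure technical spread alone. The p-values come from shifts, random placements, permutations and counts of regions within these lists, and measure no spread between replicates.

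Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Per the file headers, positions in the 2 replicate lists refer to FlyBase r5. The third list, which belongs to the series as a whole and is named as a replicate set, carries no build line, but its header states the same sequence lengths. The region caller, its thresholds, the use of the inputs and the way in which replicates were combined are not given in the sources used here. Each deposited list gives regions with a start, an end and a score, and names each region as enriched or depleted. No file of the input libraries was analysed here.

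No header or label names the unit of the score. The values themselves settled it: scores that occur more than once in a list differed from each other by log2 of ratios of whole numbers up to 40 (within 1e-07) in 546 of 13366 pairs in replicate 1, in 378 of 4851 pairs in replicate 2 and in 433 of 5356 pairs in the series list. With natural logarithms the matches were 0, 0 and 1, and with base 10 they were 6, 4 and 5. After the differences were moved at random by up to 0.001, base 2 gave 1, 0 and 0 matches. The deposited score is therefore read as a log2 ratio, whose numerator and denominator are not given in the sources used here. It is the authors' value for each region, and 1 unit is a 2-fold step of that ratio. A constant added to all scores would leave their differences unchanged, so these do not fix the zero point. The lists hold no read counts, so the sequencing depth of each library is unknown and no interval that needs it is given.

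Enriched regions were used throughout. A region counted as shared when it overlapped a region of the other replicate by at least 1 bp. Overlapping regions of both replicates were joined into groups, called shared regions, whose score in each replicate is the mean weighted by width and whose span runs from the first to the last base. Overlap and the Jaccard index (bp in both lists over bp in either) were compared with 1000 circular shifts of the replicate 2 or replicate 1 list along each arm, in 1-sided permutation tests. Score agreement is given as Spearman's rho and Pearson's r across shared regions, with 95% intervals from 1000 bootstrap draws of regions. Regions of one library are not independent replicates, and these values describe the 2 lists. Shares of the series list carry exact (Clopper-Pearson) 95% binomial intervals. These treat regions as independent draws.

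For each arm, regions per Mb and the share of the arm covered were computed from the lengths in the headers and given as mean ± SD of the 2 replicates. Median scores and widths of shared regions on X and on chromosome 4 were compared with those on 2L, 2R, 3L and 3R in 2-sided permutation tests (100000 resamples), with Benjamini-Hochberg adjustment over these 4 tests. These tests treat regions as independent draws. Intervals for X come from 1000 bootstrap draws of 1 Mb blocks. Those for chromosome 4, which spans few such blocks, come from draws of single regions. The comparison of X scores was set before the data were examined, as were the rule for naming regions and the alternatives except where stated. The tests of chromosome 4 and of widths, and the permutation of 1 Mb blocks, were added afterwards. The regions named are the 10 with the highest score in the series list that overlap a region of both replicates, and the 5 widest such regions. Alternatives were a reciprocal overlap of 50% (100 shifts), the part of each list above its median score, merging of regions within 500 bp, log2 of the score for Pearson's r, each replicate alone, and the series list in place of both replicates.

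Gene annotation on the build of the lists was not used here, because the reference table at hand refers to a later assembly (Release 6) and coordinates were not carried between builds. Occupancy of promoters of 37 gene lists drawn up beforehand was therefore not tested. Region widths and shares per chromosome arm are given instead. They do not measure occupancy along gene bodies or the position of regions relative to genes. No gene is named from its position.

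The overlap test was checked on simulated lists built from the regions of replicate 1. With 50% and 90% of its 5141 regions kept in a second list, the share expected to overlap was 57.3% and 90.3%, and 57.4% and 90.4% were recovered. The median test was checked on the 4302 shared regions of X and the autosome arms with their scores shuffled. A score of 0.2 added to the 808 regions on X was recovered as 0.18, in a shuffle that gave -0.024 with nothing added. With nothing added, 52 of 1000 runs gave a p under 0.05. The shuffle removes any likeness of regions along an arm, so these runs do not show how the test behaves where such likeness exists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.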

Results

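RNA polymerase II was mapped in Clone 8 cells, a male Drosophila line from the larval wing disc, with an antibody against the heptad repeat of the carboxy-terminal domain. The data were 1 list of enriched regions for each of the 2 ChIP replicates and 1 list for the series as a whole. Replicate 1 held 5141 enriched regions covering 19.8 Mb and replicate 2 held 5063 covering 19.2 Mb, a mean of 5102 ± 55.2 regions (SD, n = 2). They covered 14.2% and 13.8% of the sequence, leaving out the unplaced Uextra scaffold, on which no list had a region. The median score, a log2 ratio given by the authors, was 1.12 in replicate 1 and 1.14 in replicate 2. Scores reached 4.11 and 4.34, respectively. The series list held 5517 enriched regions covering 22.7 Mb, with a median score of 0.96. The depth of the libraries is unknown, since the lists hold no read counts.

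The first question was how far the replicates placed polymerase at the same sites. Of the regions of replicate 1, 4720 (91.8%) overlapped a region of replicate 2, and 4760 (94.0%) of the regions of replicate 2 overlapped one of replicate 1. After circular shifts along the arms the mean overlap was 26.6% and 26.9%, and no shift gave more than 39.3% and 39.7% (permutation p = 0.001 in each direction, 1-sided, the smallest that 1000 shifts can give). The replicates had 17.8 Mb in common, a Jaccard index of 0.837 against at most 0.113 after shifts (permutation p = 0.001, 1-sided). Among the 4022 regions that matched 1 to 1, the starts lay a median of 66.5 bp apart and the ends 65 bp apart. Both edges fell within 500 bp in 83.8% of them.

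The regions found in a single replicate were narrow and low in score. In replicate 1 these 421 regions had a median width of 1665 bp and a median score of 0.50, against 2751 bp and 1.19 for the 4720 that overlapped replicate 2. In replicate 2 the 303 such regions had medians of 1721 bp and 0.50, against 2666 bp and 1.19. Most were under 2 kb wide, 82.9% in replicate 1 and 81.2% in replicate 2, compared with 11.7% and 12.5% of the others.

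The scores of the 4443 shared regions ranked alike in both replicates. Spearman's rho across regions was 0.947 (95% interval 0.943 to 0.951) and Pearson's r was 0.949 (0.945 to 0.953). These values compare 2 libraries, and regions are not independent replicates. The median shared region scored 1.22 in both replicates, and 96.8% of shared regions differed by less than 0.5. Of the 42 shared regions with a mean score of at least 3, 37 scored higher in replicate 2, by a median difference of 0.14 over the 42.

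**Figure D1:**
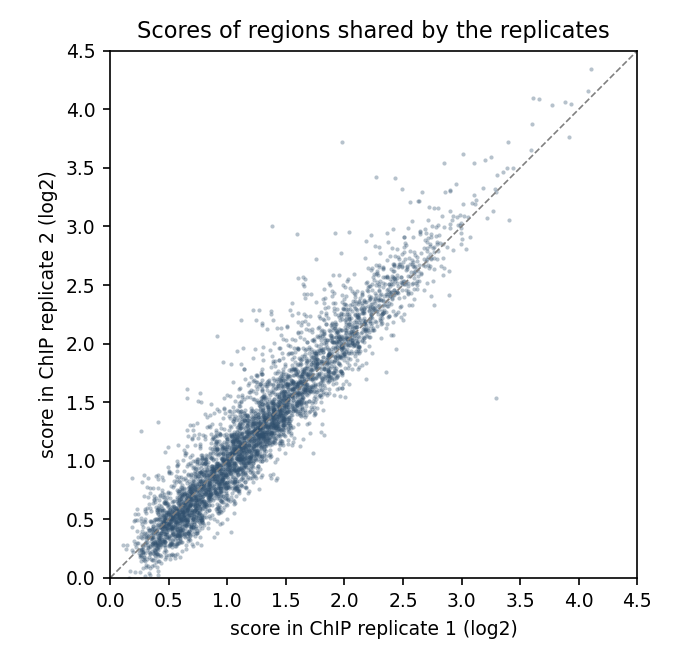
Score of each of the 4443 shared regions in ChIP replicate 1 (x axis, log2 ratio) and ChIP replicate 2 (y axis, log2 ratio), 1 point per region, with the dashed line marking equal scores. The points lie along the line, with a Spearman's rho of 0.947, and mostly above it where the mean score is 3 or more.

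The list for the whole series was then set against the replicates. Of its 5517 regions, 4316 overlapped a region of both replicates (78.2%, exact 95% interval 77.1 to 79.3%). A further 352 overlapped replicate 1 alone and 263 replicate 2 alone. The remaining 586 regions (10.6%, 9.82 to 11.5%) overlapped neither replicate. Those 586 had a median width of 1249 bp and a median score of 0.38, whereas the regions found in both replicates had medians of 3134 bp and 1.16. Nearly every replicate region was represented, 5102 (99.2%) of those of replicate 1 and 5041 (99.6%) of those of replicate 2. The narrowest region was 1001 bp in the series list, 1301 bp in replicate 1 and 1303 bp in replicate 2, and 331 of the 586 were narrower than 1300 bp.

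Among the 10 regions named for their score, the width ran from 2667 to 12281 bp with a median of 3099 bp. These regions were taken by their score in the series list, while the scores given are means of the 2 replicates, which order them differently. The highest by either score lay on 2R (13029718 to 13034652, FlyBase r5, as are all positions), 4935 bp wide, with a score of 4.22 ± 0.16 (SD, n = 2). Read as a log2 ratio without an added constant, this score is a ratio of 18.7 on the linear scale. It was followed by a 2741 bp region on 2L (13214654 to 13217394) with 4.11 ± 0.05 and a 2739 bp region on 3R (19683856 to 19686594) with 3.99 ± 0.08. Another region on 2L (13243272 to 13246102) lay 25.9 kb from the one at 13214654 and scored 3.87 ± 0.30. Further along 2L, a 5863 bp region (21536784 to 21542646) scored 3.85 ± 0.34 and a 3131 bp region (21213722 to 21216852) scored 3.97 ± 0.13. On 3L, a 2667 bp region (3089646 to 3092312) scored 3.84 ± 0.11 and an 8299 bp region (11242854 to 11251152) scored 3.90 ± 0.19. A 3067 bp region on the unplaced scaffold U (9709792 to 9712858) scored 3.74 ± 0.19. The tenth by the series list, on 3R (17120962 to 17133242), was split differently by the replicates. Replicate 1 had a region with 3.49 (17121035 to 17126988) beside a weaker one with 1.04 (17127069 to 17136590), and replicate 2 had a single region with 3.72 (17120969 to 17129662). None of these 10 regions lay on X or on chromosome 4.

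The widest regions had moderate scores. The widest spanned 122149 bp on 3L (22279990 to 22402138) and was a single region in each replicate, with a score of 1.46 ± 0.05. A 58935 bp region on 3R (19114014 to 19172948) was likewise single in both and scored 1.59 ± 0.06. The other wide regions were broken up in the replicates. On 3R (21340508 to 21439052) a 98545 bp region of the series list held 3 regions of replicate 1 and 5 of replicate 2, with a mean score of 1.00 ± 0.07. A 95257 bp region on 3L (5147412 to 5242668) held 7 and 12, with 0.92 ± 0.05, and a 92155 bp region on 3R (4892702 to 4984856) held 3 and 11, with 0.86 ± 0.15.

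Across the lists, regions were a few kb wide, with a median of 2586 ± 33.2 bp (SD, n = 2). Regions of 2 to 5 kb made up 64.6% ± 0.8 of each replicate list and 48.4% ± 0.6 of the sequence it covered. Those of 10 kb or wider were 4.41% ± 0.28 of the regions and 19.6% ± 1.1 of the sequence covered. Median scores were 0.42 ± 0.03 under 2 kb, 1.18 ± 0.01 from 2 to 5 kb, 1.54 ± 0.02 from 5 to 10 kb, 1.75 ± 0.04 from 10 to 20 kb and 1.61 ± 0.02 at 20 kb or wider. Across regions, score rose with width in each list, with a Spearman's rho of 0.645 in replicate 1, 0.597 in replicate 2 and 0.622 in the series list. The highest score among regions of 20 kb or wider was 3.00 in replicate 1 and 2.89 in replicate 2, below the 4.11 and 4.34 reached between 2 and 5 kb. Widths were not set against gene lengths, since no annotation on this build was used.

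The called regions were concentrated on the main arms. The 4 large autosome arms held 77.2% ± 0.5 of the regions, X 19.2% ± 0.5 and chromosome 4 1.49% ± 0.09 (SD, n = 2). The heterochromatic and unplaced scaffolds that had regions, 19.3 Mb in all, held 2.12% ± 0.08. Only 1.68% ± 0.20 of those scaffolds was covered, compared with 15.4% ± 0.3 of the autosome arms. Sequence in which short reads cannot be placed was not told apart from sequence without polymerase. On YHet, 347038 bp of sequence placed on the Y chromosome, each replicate had 1 region. The shares were uneven among the autosome arms, from 13.8% ± 0.5 on 2L and 14.2% ± 0.2 on 3L to 16.3% ± 0.3 on 3R and 17.2% ± 0.04 on 2R. The number of regions was highest on 2R, at 48.0 ± 0.2 per Mb, against 37.5 ± 0.9 on 2L, 38.5 ± 0.5 on 3L and 40.0 ± 0.1 on 3R.

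**Figure D2:**
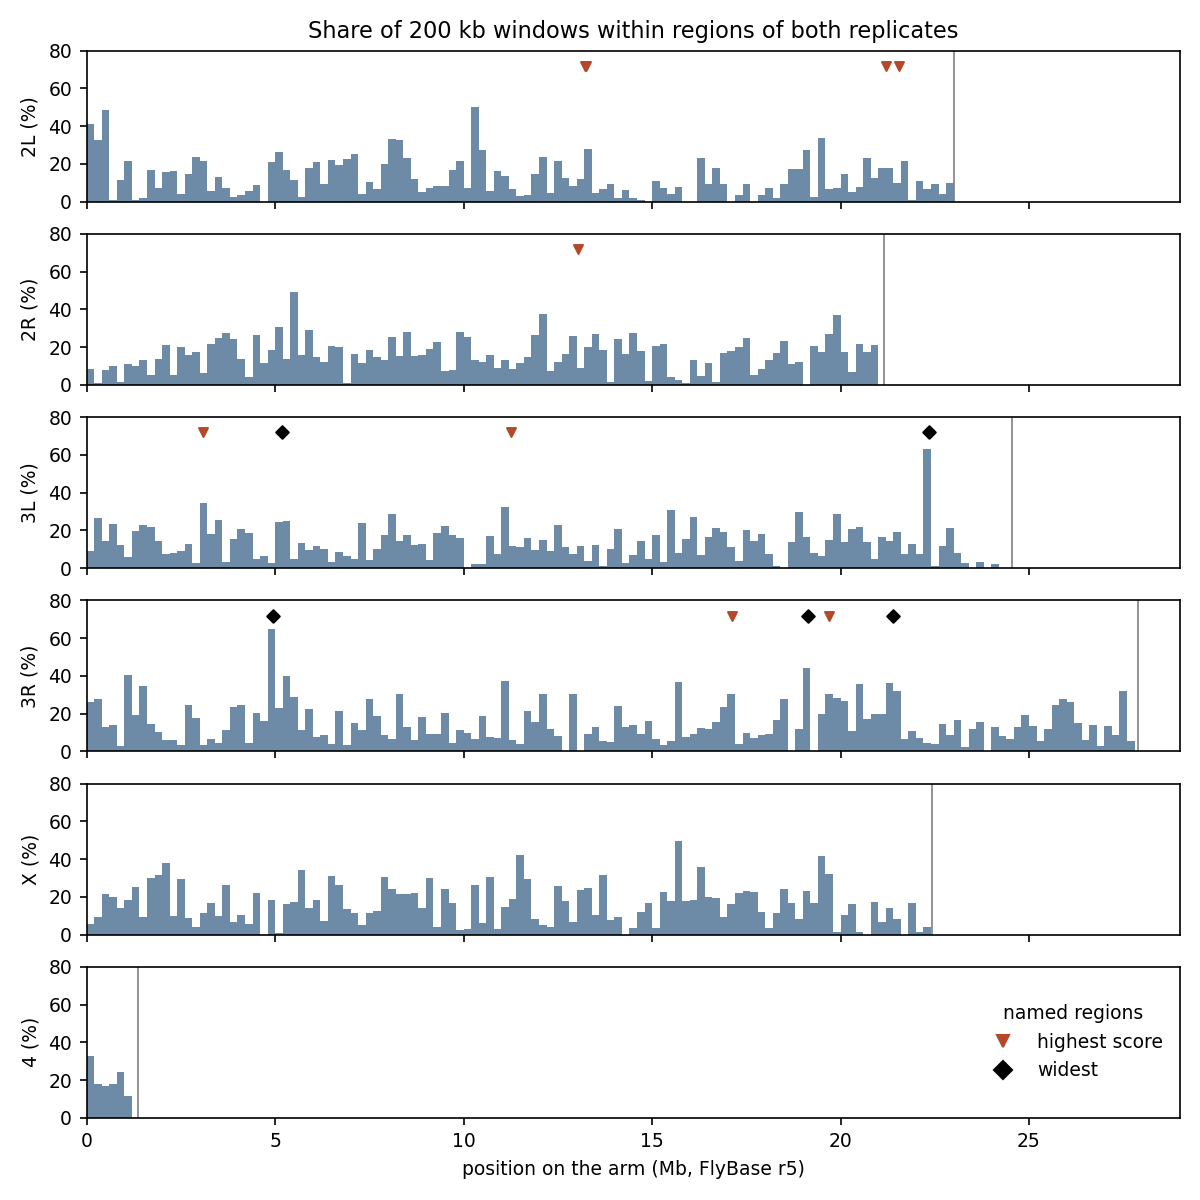
Share of each 200 kb window (y axis, %) that lies within regions of both replicates, along each arm (x axis, Mb, FlyBase r5), with triangles for the 9 highest-scoring named regions on these arms, diamonds for the 5 widest and a grey line at the end of each arm. The tallest window, on 3R from 4800001, reached 64.6%, and 21 of the 599 windows had none.

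The cells are male, with a single X that is subject to dosage compensation, so X was compared with the autosome arms. X was covered to a larger extent than any autosome arm in both replicates, 17.9% ± 0.3 against 15.4% ± 0.3 for these arms together, a ratio of 1.17 ± 0.003 (SD, n = 2). The number of regions per Mb differed less, 43.7 ± 1.6 on X and 40.8 ± 0.2 on the autosome arms (ratio 1.07 ± 0.03), and was lower on X than on 2R. The 808 shared regions on X had a higher median score than the 3494 on the autosome arms, 1.35 against 1.18. The difference of 0.17 (95% interval 0.11 to 0.23) is a 1.13-fold step of the ratio (permutation p = 1e-05, 2-sided, the smallest the resamples can give, Benjamini-Hochberg adjusted p = 4e-05). That test treats regions of the same 2 libraries as independent draws. With X as 1 of 5 arms, a permutation of whole arms could give no p under 0.2. The difference was of the same direction in each replicate list, with 0.13 in replicate 1 and 0.14 in replicate 2. It was 0.0487 in the series list, where it did not pass the test (permutation p = 0.165), and -0.0207 among regions that scored above the median of each list, a selection by the value compared (permutation p = 0.561).

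The difference on X was found among weaker regions. At the 5th percentile X scored 0.56 against 0.38 on the autosome arms, a difference of 0.18 (0.15 to 0.23), and at the 25th percentile the difference was 0.23 (0.15 to 0.29). At the 95th percentile X scored 2.49 and the autosome arms 2.49, a difference of -0.0058 (-0.13 to 0.10). The highest shared score on X was 3.45, below the maxima of 3.90 to 4.22 on the autosome arms. Shared regions on X were also wider, with a median of 3349 bp against 2908 bp (difference 440.5 bp, 95% interval 206 to 652, permutation p = 2e-05, adjusted p = 4e-05). The difference in width was smaller within single lists, 192 bp in replicate 2 and 120.5 bp in replicate 1, and in replicate 1 it did not pass the test (permutation p = 0.0765). Nor did it in the series list, at 140 bp (95% interval -108 to 407, permutation p = 0.0700). Regions of 10 kb or wider made up 10.9% of the shared regions on X, 88 in number, and 4.14% to 7.22% on the autosome arms.

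**Figure D3:**
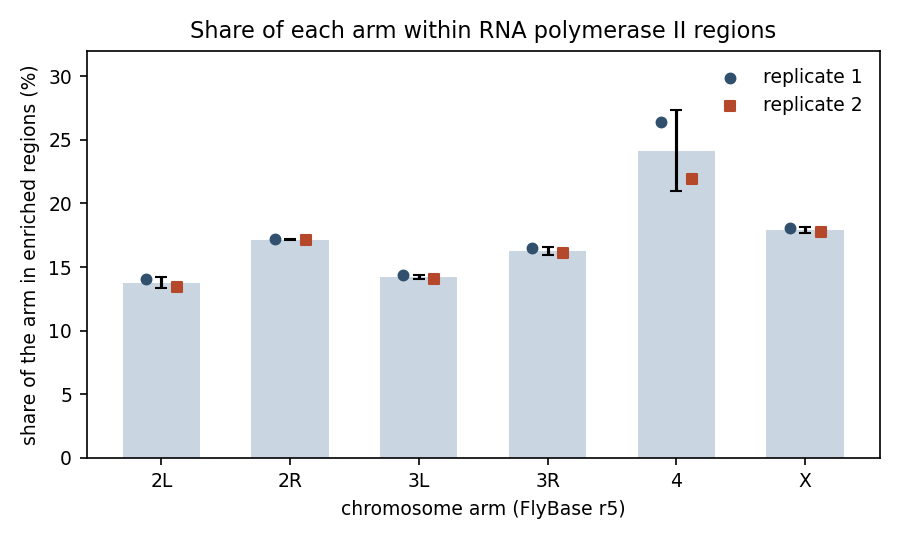
Share of each chromosome arm (y axis, %) within enriched regions, with bars for the mean of the 2 ChIP replicates, error bars for the SD and points for each replicate. X lies above the arms 2L, 2R, 3L and 3R, and chromosome 4 is highest, at 26.4% in replicate 1 and 21.9% in replicate 2.

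Chromosome 4, a short autosome largely made of heterochromatin, had the largest share of its sequence in regions. They covered 24.1% ± 3.2 of it (SD, n = 2), 1.57 ± 0.18 times the share of the large autosome arms, and numbered 56.2 ± 4.2 per Mb. Among regions above the median score of each list, this ratio was higher on X, at 1.36, than the 1.17 of chromosome 4. The replicates differed here, with 80 regions in replicate 1, of which 15 were absent from replicate 2, and 72 in replicate 2, all of them found in replicate 1. The top scores were low. The 59 shared regions had a median of 0.98, a difference of -0.19 from the autosome arms that did not pass the test (permutation p = 0.0803, 2-sided, adjusted p = 0.0878). The low end of the range was not lower on chromosome 4. The difference was 0.11 (95% interval -0.0087 to 0.17) at the 5th percentile and -0.069 (-0.17 to 0.12) at the 25th. Higher in the range the difference was larger. At the 95th percentile the score was 1.58 against 2.49, a difference of -0.91 (95% interval -1.12 to -0.82), and no shared region on chromosome 4 exceeded 1.73.

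**Figure D4:**
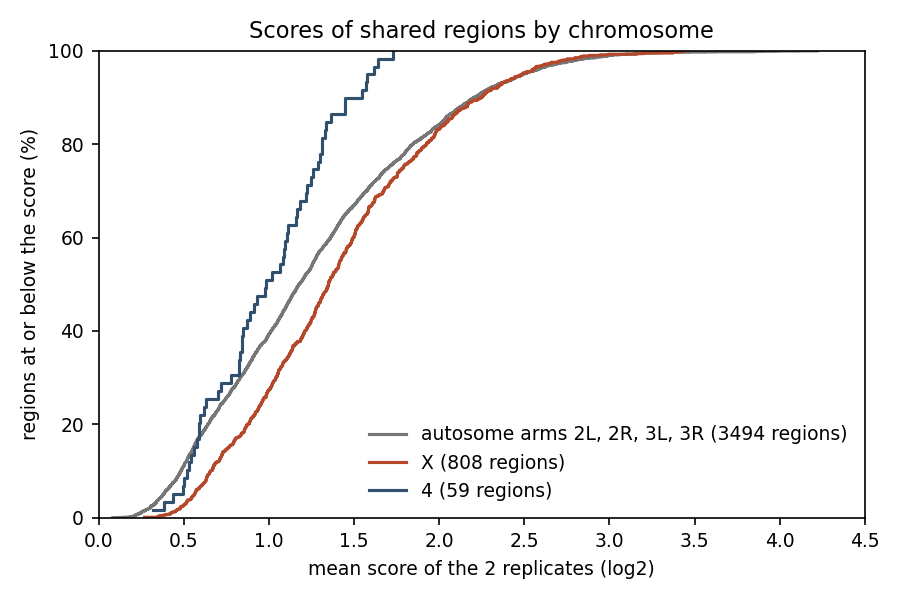
Cumulative share of shared regions (y axis, %) at or below each score (x axis, mean of the 2 replicates, log2 ratio), for the large autosome arms, X and chromosome 4. The curve for X starts to the right of that for the autosome arms and meets it near the top, where the 95th percentiles are both 2.49, and the curve for chromosome 4 ends at 1.73.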

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

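The series list named 17 regions as depleted, in addition to the enriched regions on which the comparisons rest. They were flagged because no comparison used them. All were narrow, from 1569 to 1865 bp, and their scores lay just below zero, from -0.09 to -0.002. They were on 2L, 2R, 3L and 3R. Of the 17, 15 overlapped a region that a replicate list named as enriched, 8 in replicate 1 and 8 in replicate 2, with 1 of them (3L, 15109076 to 15110796) in both. The series list also held 63 enriched regions with scores under 0.1. Replicate 2 named a single region as depleted (2L, 2829370 to 2831111, score -0.04), which overlapped an enriched region of the series list, and replicate 1 named none. No explanation was tested for these regions.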

How the results depend on the processing

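The permutation of 1 Mb blocks, the comparisons of widths and those of chromosome 4 were chosen after seeing the data; the other alternatives were set before the data were examined. Of 46 alternative values over 13 results, 30 stayed on their side of the threshold or within the spread. The overlap of the replicates was 84.4% to 92.6% of replicate 1 and 85.7% to 94.4% of replicate 2 under a reciprocal overlap of 50%, the part of each list above its median score and merging within 500 bp, each above all shifts. Pearson's r moved to 0.912 on log2 of the score. The share of series regions in both replicates moved to 72.6% with reciprocal overlap and 81.3% above the median score. The higher median score on X was 0.13 to 0.14 in single replicates and had a permutation p of 0.0001 with 1 Mb blocks (the smallest these can give), but was 0.0487 in the series list (permutation p = 0.165) and -0.0207 above the median score (p = 0.561). The greater width on X was 120.5 bp without replicate 2 and 192 bp without replicate 1, and 140 bp in the series list (permutation p = 0.0700). It was 558.5 bp above the median score (permutation p = 0.00166), and the permutation of 1 Mb blocks gave a p of 0.0005. On chromosome 4 the score difference of -0.19 became -0.24 in the series list (permutation p = 0.0348) and -0.40 above the median score (p = 0.00435). Above the median score, regions per Mb on X relative to the autosome arms rose to 1.24, the covered share on X to 1.36 (1.24 in the series list), the median width to 3442 bp, and the covered share of chromosome 4 dropped to 1.17. The share of regions on heterochromatic and unplaced scaffolds was 3.24% in the series list and 1.88% above the median score. Keeping only scores above the median selects regions by the value compared, so its score differences do not test X or chromosome 4, and for the other changes the cause was not tested.

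No paired analysis was possible because no values of the input libraries were analysed here and the 2 ChIP replicates form a single group. Promoter windows of 500 bp, a least gene length of 4 kb and all alternatives for promoter occupancy of gene lists were not run, for lack of an annotation on the build of the lists. With depth unknown, a region missing from a list cannot be told from one that was too thinly read to be called.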

Other observations

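The tests in this part were chosen after the results were seen. Polymerase regions left long stretches of the arms empty. On the 6 main arms, 211 stretches of 100 kb or more had no region in any of the 3 lists, and together they made up 32.7 Mb, or 27.2% of these arms. Placing the regions at random along each arm gave 26.3 such stretches on average and never more than 39 in 1000 placements (permutation p = 0.001, 1-sided, the smallest they can give). The longest lay on X (20530533 to 20898011, 367 kb), followed by 2L (16911347 to 17259666, 348 kb), X (14144847 to 14473656, 329 kb) and 2L (4466163 to 4794078, 328 kb). The longest stretch in any of the random placements was 333 kb, longer than the stretches of 329 kb and 328 kb. The 211 stretches took up 32.9% of 2L but 17.9% of 2R, and none occurred on chromosome 4. At the other extreme, the 200 kb windows most covered in both replicates began at 4800001 on 3R (64.6%) and at 22200001 on 3L (63.2%), each dominated by a wide region named in the report, and at 10200001 on 2L (50.1%). Which genes lie in these stretches was not examined, and sequence in which short reads cannot be placed was not told apart from sequence without polymerase.

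The ends of the assembled arms differed in the share covered. Here too, sequence in which short reads cannot be placed was not told apart from sequence without polymerase. The separate heterochromatic scaffolds were left out. The 1 Mb nearest the centromere is thus the end of an arm's own sequence on that side. In the 1 Mb nearest the centromere, regions covered 1.71% ± 0.21 of 3L, 6.66% ± 0.20 of 2R, 7.01% ± 0.42 of X and 9.10% ± 0.16 of 2L (SD, n = 2), in each case less than in the rest of the arm, where the shares ran from 13.3% on 2L to 18.6% on X. On 3R the same part was covered to 18.2% ± 0.3, more than the 16.3% ± 0.3 of the rest. The 1 Mb at the other end was covered more than the rest of the arm on 2L (28.8% ± 1.7) and 3L (18.9% ± 0.7 against 14.6% ± 0.2), and less on 2R (16.5% ± 0.8 against 17.7% ± 0.01), 3R (14.5% ± 0.2) and X (15.5% ± 0.5). Neighbouring shared regions did not have alike scores (Spearman's rho -0.002 over 4355 pairs, permutation p = 0.916). Their widths were weakly related (rho 0.06, permutation p = 0.001, the smallest that 1000 shuffles can give).

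Weaker regions on X scored higher than those on the autosome arms, and the strongest did not. The same rise of all called regions on X does not describe the pattern. At the 95th percentile the difference was -0.0058, and its upper bound of 0.10 lay under the 0.17 seen at the median. What dosage compensation would do to the score cannot be said, because the numerator and denominator of the ratio are not given in the sources used here. In the series list the 95th percentile was lower on X, by a difference of -0.123 (-0.218 to -0.016). Loss of weak regions on X from the shared set does not account for the rise at the low end. Over all regions of each replicate list the 5th percentile was also higher on X, by 0.181 (0.150 to 0.205) in replicate 1 and 0.194 (0.151 to 0.233) in replicate 2. Regions on X were, however, more often absent from the other replicate (10.4% against 7.06% in replicate 1, 7.55% against 5.40% in replicate 2, Fisher's exact test, adjusted p = 0.00143 and 0.0202). The difference of the medians was 0.17 among shared regions, and 0.13 and 0.14 over all regions of replicates 1 and 2. A contribution of such loss to the median difference is thus not excluded. Whether X holds a different mix of genes was not tested. Whether a region on the single X had to reach a higher score to be called remains open. The rise of 0.18 at the 5th percentile of shared regions is the pattern itself. The lowest scores on X, 0.21 in replicate 1 and 0.11 in replicate 2, lay under the 5th percentiles of the autosome arms (0.36 and 0.30). They lay above the lowest scores on those arms, 0.10 in replicate 1 and 0.003 in replicate 2. In the series list the lowest scores were 0.079 on X and 0.0017 on those arms. A minimum also depends on the number of regions, 1004 on X and 3951 on the autosome arms in replicate 1.

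Chromosome 4 combined wide cover with low top scores. A small number of regions does not account for the low top scores. None of 10000 random draws of 59 shared regions from the autosome arms had a 95th percentile under 1.81, against 1.58 on chromosome 4. That percentile had prompted the draws, and the cover was not tested in this way. Width did not account for the low scores either. Shared regions on chromosome 4 had a median width of 3418 bp against 2908 bp on the autosome arms. The difference of 510 bp (95% interval -16.5 to 1580) did not pass the permutation test (p = 0.0878, adjusted p = 0.0878). Set against the 20 autosome arm regions nearest in width, regions on chromosome 4 scored lower by a median difference of -0.38 (95% interval -0.48 to -0.23). Of the 59, 45 were lower. That outcome could be foreseen, because score rose with width in each list. Gene density, repeats and the heterochromatic state of the chromosome remain open as untested. In the series list 1 region on chromosome 4 (1323742 to 1352452) ended 595 bp past the length that the header gives for it.

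High scores at the smallest widths of the series list mostly had no counterpart in the replicates, whose lists hold no region narrower than 1301 bp. In the series list, 14 regions narrower than 1300 bp had a score of at least 2.5. Of these, 13 overlapped neither replicate and 1 overlapped a single replicate. Over all scores, the share in neither was 87.2% from 1000 to 1100 bp and 87.9% from 1100 to 1200 bp. From 1200 to 1300 bp it was 73.4%. Lacking a counterpart was thus not particular to the high scores. Of the 14, 7 had the identical score of 3.15 and a width of 1001 bp. Among them were 2L 4922162 to 4923162 and 3R 23999604 to 24000604, chosen after their values were seen. Scores built from small whole numbers are a candidate explanation. Leaving out the 7 identical scores, which prompted the test, 5 of the other 7 (71.4%) had a score that occurred more than once in the list. Among wider regions that scored as high it was 1 of 190 (0.526%, Fisher's exact test, p = 5.3e-08). Regions that repeat a score do so with each other, so these are not independent outcomes and the p describes the list alone. Over all scores of the series list, narrow regions also repeated scores more often, 19.8% under 1.5 kb against 2.34% from 2 to 5 kb. The smaller least width of the series list remains open as well, since the share of its regions in neither replicate was 65.2% from 1300 to 1400 bp and 73.4% just below (Fisher's exact test, p = 0.222), with no clear step at that width. Repeated sequence at these positions was not examined, and no biological explanation was tested.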
